A study of Rattus norvegicus with 36 samples.

How the data were processed

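Liver RNA of 36 male Wistar rats was measured on Illumina RatRef BeadChips, 12 arrays on each of 3 slides. Per the labels, total RNA was extracted with TriReagent, checked on an Experion analyser and turned into biotin-labelled cRNA with the Illumina TotalPrep kit. The deposited non-normalized file holds the mean bead intensity of 22523 probes per array, on a linear scale. Beside each intensity the authors deposited a detection p-value from the array's negative controls. The authors also deposited a value table of normalised intensity. Its method, including its scale factor and any background step, is not given in the sources used here. Its values are linear, run from 183 to 37140, have a column median of 212 in every array and keep the rank order of the raw values in every array (Spearman 1). The direction of its scale is known from that rank order, while its scaling and centring stay unknown. Image processing, scanner settings, vitamin A doses and times are not given in the sources used here.

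Groups were taken from the labels: diet (VAS or VAD), operation (sham or BDL) and injection (vehicle or VITA), with 5 rats in each BDL group and 4 in each sham group. No array was left out. Slides hold unequal parts of the groups, and the replicate numbers of different groups do not pair: in 0 of 8 comparisons did every same-number pair correlate above 0.1 (range -0.19 to 0.41). Arrays had 29.2% to 38.1% of probes detected at p below 0.01 (6577 to 8587 probes) and median raw intensities of 108.2 to 145.3, with the lowest intensity of an array at 78.8 to 103.8. This signal over background is the depth of an array. Correlations of arrays within a group were 0.9604 to 0.9921, and 0 arrays were identical.

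All values were computed with R 4.3.3 and limma 3.58.1; tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Intensities were background corrected and quantile normalised with neqc, offset 16, with negative control levels inferred from the detection p. Probes detected on at least 4 arrays were kept (9545), and the probe with the highest mean stood for each gene, giving 9314 genes; 218 genes had more than 1 such probe. At most 5 of these genes had probes called in opposite directions in any comparison. Probe names were matched to a RefSeq name table, used for names only: 9578 by current symbol, 1824 by gene ID and 5419 by synonym, 74.7% in all, while 5702 kept the name in the file. A linear model with 8 group means (28 residual degrees of freedom) gave 11 contrasts with moderated errors. p is two-sided, adjusted by Benjamini and Hochberg over all genes, and a gene is called changed at an adjusted p under 0.05. A called change in a gene below background on every array of 1 of 2 groups is given as a lower bound.

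Gene lists were tested with camera on the moderated statistics with a preset correlation of 0.01, again with an estimated correlation, and with fry. List p-values are two-sided and adjusted over the lists of a comparison. Of 27 lists, the B and plasma cell list had 2 genes tested, under the minimum of 3, and was not tested. The named genes follow a rule: a panel of 26 genes, 19 of them tested; the largest called changes in each direction, 8 in the main comparisons and 4 in the others; and up to 4 genes per list with the largest change. Names of the LOC, RGD or MGC kind were passed over. The values of 1 panel gene are not reported here. Lrat, Dhrs3 and Acta2 have no probe under that name and were not analysed here. Tnf and S100a9 were detected on 0 arrays, Cd3e on 2 and Cd79b on 3.

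Comparisons, lists, the named-gene rule and the alternatives were chosen before the data were examined. The alternatives were normexp with offset 50 and quantile normalisation, median scaling, the authors' value table, no filter, a stricter filter, every probe on its own, slide or replicate number as a block, a fit to only the groups of the comparison, and each array left out in turn. Leaving out slide 3 was added after seeing the data. Inverse or shared relations between contrasts were compared with 100 simulations without true effects. Overlaps of called genes were compared with such simulations and with fits that divide the shared arrays, both added after the data were seen. The model was tested on simulated data with 200 of 9314 genes changed. In VAD against VAS sham vehicle it recovered 20.9%, 76.2% and 98.6% of changes of log2 0.5, 1 and 2, and 6.4% of its calls were false. The diet by surgery interaction recovered 6.7%, 68.4% and 91.2%, with 3.6% of calls false. Separation of groups was also compared with other splits of the same arrays.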

Results

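The series asked what lack of vitamin A does to the rat liver when bile flow is blocked. Male Wistar rats on a vitamin A sufficient (VAS) or deficient (VAD) diet had bile duct ligation (BDL) or a sham operation, and received daily retinyl palmitate (VITA) or vehicle. Each of the 4 BDL groups held 5 rats and each of the 4 sham groups held 4, with 1 liver array per rat. Changes are log2 differences between group means with the standard error (SE) in brackets, and p is limma's two-sided p adjusted over 9314 genes. A called gene below background on every array of 1 of 2 groups is given as "at least" a fold, because its level there is known only to lie under the background. Gene names come from the array file and a reference name table. The number of arrays limits the precision of every value below.

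The first principal component held 44.1% of the variance and separated the operations, with VAD BDL vehicle rats farthest from sham. The second held 9.3% and was higher on slide 3, so the comparisons below are also given with slide as a block or within slides. Called genes were chosen from the same arrays, so high shares moving the same way within slides are partly built in.

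**Figure D1:**
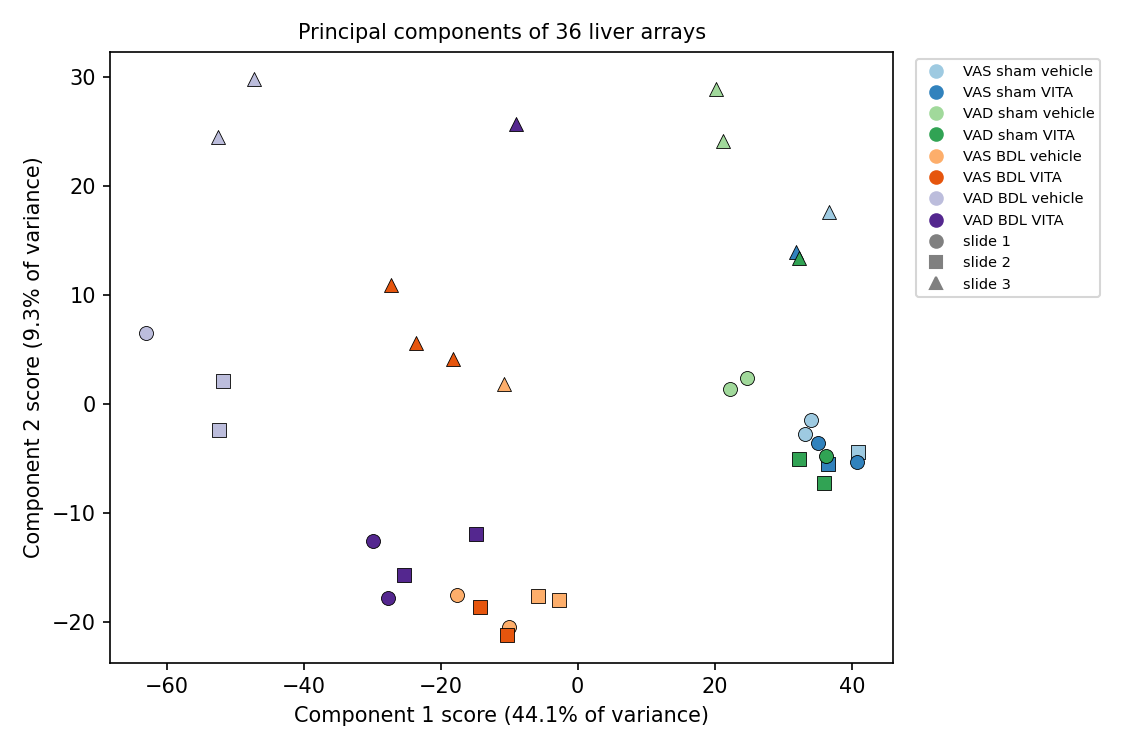
Principal components 1 and 2 of normalised log2 intensity over the tested genes, 1 point per rat, coloured by group. BDL rats lie left of sham rats, and VAD BDL vehicle rats lie farthest left.

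The first comparison asked what deficiency alone changed in sham livers. It changed 103 genes, 64 higher and 39 lower, 68 of them at least 2-fold (4 rats per group). Cyp2c12, a cytochrome P450 found mainly in female rat liver, rose 55.7-fold (5.80 (SE 0.36), adjusted p = 3.1e-13), from 8.32 ± 0.35 to 14.12 ± 0.12 (mean log2 intensity ± SD). Cyp2c13, a male-predominant P450, fell 46.0-fold (-5.52 (0.51), adjusted p = 5e-09), and Cyp2c22, a P450 known to respond to retinoic acid, fell 15.4-fold (-3.94 (0.34), adjusted p = 1.3e-09). Obp3, of the male-predominant urinary protein family, fell 15.0-fold (-3.91 (0.48), adjusted p = 2.1e-06), and Akr1c2, a steroid-handling reductase, fell 16.9-fold (-4.08 (0.75), adjusted p = 0.0015). Scd2, a fatty acid desaturase, rose by 1.72 (0.23, adjusted p = 9.4e-06) and Cav2, a caveolar coat gene, by 1.66 (0.23, adjusted p = 1.4e-05). Without VAD sham vehicle replicate 2 the fall of Cyp2c13 was 70.0-fold (-6.13), and without VAS sham vehicle replicate 2 that of Obp3 was 22.6-fold (-4.50). In each of these genes every VAD value lay on the same side of every VAS value. The male-specific Cyp2c11 did not pass (-0.54 (0.50), adjusted p = 0.81).

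Of the damage genes in sham livers, Lcn2 (2.66 (0.75), adjusted p = 0.078) and Timp1 (0.96 (0.27), adjusted p = 0.078) did not pass, and Cyp26a1, the retinoic acid-degrading enzyme, was detected on 0 of 4 VAD and 2 of 4 VAS arrays (adjusted p = 0.63). Cyp7a1 (1.70, adjusted p = 0.18) passed without VAD sham vehicle replicate 1 (2.54, adjusted p = 0.0039). Col1a1, Krt7 and Ccl2 were below background in both groups. The macrophage list rose (median 0.51, camera adjusted p = 1.7e-07, 0.14 with an estimated correlation), with 1 of 18 genes passing over all genes and 9 over the list alone. Endothelial genes (0.52, adjusted p = 0.0001, estimated 0.062) and cytokines (0.33, 0.06 with undetected genes at their bound, adjusted p = 0.00036, estimated 0.062) also rose, and interferon-stimulated genes fell (-0.40, adjusted p = 0.002, estimated 0.22). 4 weaker list calls were acute-phase (0.14, adjusted p = 0.011, estimated 0.21, without VAD sham vehicle replicate 1 0.15, adjusted p = 0.067), neutrophil (0.30, 0.17 with bounds, adjusted p = 0.02, estimated 0.23, adjusted p = 0.14 without VAD sham vehicle replicate 2 and 0.082 without VAS sham vehicle replicate 4), antigen presentation (0.16, adjusted p = 0.016, estimated 0.22, adjusted p = 0.054 without VAD sham vehicle replicate 2) and endoplasmic reticulum stress (0.16, adjusted p = 0.046, estimated 0.14, slide as a block 0.10, adjusted p = 0.11). The endoplasmic reticulum stress call also ended without VAD sham vehicle replicate 2 (adjusted p = 0.11) or 4 (0.06) or VAS sham vehicle replicate 2 (0.076) or 4 (0.1), and the neutrophil call in the authors' table (0.07, adjusted p = 0.16) and with no filter (adjusted p = 0.45).

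With slide as a block the sham diet effect counted 132 genes, and all 103 genes moved the same way within slides 1 and 3; slide 2 holds no VAD sham vehicle array. The count was 37 without slide 3 and 41 in a fit to only the groups of the comparison. It fell to 49 without VAS sham vehicle replicate 3 and to 64 without VAD sham vehicle replicate 4, and the share of higher calls fell from 62.1% to 46.1% under median scaling.

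The next comparison asked what ligation did to vitamin A sufficient livers. It changed 1617 genes (977 higher, 640 lower, 584 at least 2-fold, 5 BDL and 4 sham rats). Abcb1b, a drug efflux pump, rose 50.7-fold (5.66 (0.42), adjusted p = 8.4e-12, detected on 1 of 4 sham arrays) and Lcn2, an iron-scavenging acute-phase protein, 29.8-fold (4.90 (0.71), adjusted p = 6e-06). The bile duct keratin Krt19 rose 6.53-fold (2.71 (0.37), adjusted p = 1.7e-06), and the metalloproteinase inhibitor Timp1 rose 2.33-fold (1.22 (0.26), adjusted p = 0.00081). Cyp8b1, which makes cholic acid, fell 29.8-fold (-4.90 (0.71), adjusted p = 5e-06), and the bile salt importer Slc10a1 fell 1.94-fold (-0.95 (0.24), adjusted p = 0.0052). Cyp7a1, the first enzyme of bile acid synthesis, rose 11.8-fold (3.56 (0.54), adjusted p = 1.3e-05). Mup4l3 fell 82.1-fold and Obp3 69.8-fold, both male-predominant urinary protein genes. Nr0b2 (0.56, adjusted p = 0.44), Abcb11 (0.16) and Alb (-0.01) did not pass, nor did Ccl2, which 2 of 5 BDL and 0 of 4 sham arrays detected (adjusted p = 0.55). Abcb11 lay near the background (6.03 in sham rats, detected on 3 of 4 arrays, and 6.19 after ligation), so a change in it could be missed. Alb stood at 14.68 in both groups, and saturation at that level was not tested.

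In the same livers the chemokine Cxcl16 rose by 3.02 (0.30, adjusted p = 8.6e-09), the class II antigen-presenting genes RT1-Ba by 2.35 (0.26, adjusted p = 6.5e-08) and RT1-Da by 2.12 (0.23, adjusted p = 4.1e-08), the macrophage galectin Lgals3 by 1.95 (0.23, adjusted p = 2e-07), and collagen Col1a2 by 1.70 (0.26, adjusted p = 1.1e-05). The peroxisomal oxidase Acox2 (-1.35 (0.26), adjusted p = 0.00025) and the glucose-sparing kinase Pdk4 (-1.46 (0.28), adjusted p = 0.00026) fell. 3 lists held with an estimated correlation: macrophage genes (median 1.26, 14 of 18 higher, 16 over the list alone, adjusted p = 1.7e-12, estimated 0.023), antigen presentation (1.17, 10 of 16, 12 alone, adjusted p = 4.1e-09, estimated 0.0057) and cytokines (0.79, 15 of 29, 19 alone, adjusted p = 2.2e-06, estimated 0.01). Matrix genes (0.50, or 0.24 with bounds, 14 of 38, 16 alone, adjusted p = 9.4e-07) and cell cycle genes (0.72, or 0.24 with bounds, 14 of 30, 18 alone, adjusted p = 6.9e-08) rose, and fatty acid oxidation genes fell (-0.57, 13 of 32, 18 alone, adjusted p = 5.4e-10); their adjusted p was 0.15, 0.18 and 0.065 with an estimated correlation.

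For this ligation effect the slide-block count was 1982, and 100%, 99.8% and 99.3% of the genes moved the same way within slides 1 to 3; matrix medians within slides were 0.53, 0.45 and 0.77. Median scaling moved the median of all genes from -0.011 to 0.116 and the share of higher calls from 60.4% to 76.8%.

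What ligation did without vitamin A was asked next. In VAD rats it changed 3769 genes (1936 higher, 1833 lower, 1378 at least 2-fold, 5 and 4 rats). Lox, which crosslinks collagen, rose 53.2-fold (5.73 (0.44), adjusted p = 3.5e-12), Mmp12, a macrophage elastase, 40.9-fold, Spp1, osteopontin, 34.4-fold, and Timp1 14.6-fold (3.87 (0.26), adjusted p = 3.2e-13). Col6a3 rose by 3.72 (0.25, adjusted p = 3.2e-13), Col1a1 at least 3.72-fold and Ccl2, a monocyte chemokine, at least 6.48-fold. The broad protease inhibitor A2m rose 17.1-fold (4.10 (0.93), adjusted p = 0.00058). Cyp2c11 fell 88.0-fold (-6.46 (0.48), adjusted p = 2.1e-12), Car3 85.3-fold (129.0-fold without VAD BDL vehicle replicate 4), and Nr0b2, a repressor of bile acid synthesis, 6.79-fold (-2.76 (0.43), adjusted p = 3.7e-06). Slc10a1 fell 4.12-fold (-2.04 (0.24), adjusted p = 3.2e-08), while Cyp8b1 did not pass (-0.69 (0.71), adjusted p = 0.46). The histidine-degrading Hal (-2.88 (0.27), adjusted p = 3.4e-10), the urea cycle gene Otc (-1.49 (0.18), adjusted p = 5.7e-08) and the desaturase Fads2 (-3.74 (0.41), adjusted p = 4.9e-09) fell.

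9 lists held with an estimated correlation after ligation in VAD rats. Matrix genes rose most (median 2.28, 1.83 with bounds, 36 of 38 higher, 36 alone, adjusted p = 3e-24, estimated 0.0048), then macrophage (1.78, 15 of 18, estimated 0.021), cholangiocyte (1.60, 11 of 16, estimated 0.01), neutrophil (1.5, 7 of 8, estimated 0.049), cell cycle (1.46, 0.91 with bounds, 27 of 30, estimated 0.049) and cytokine genes (1.37, 0.99 with bounds, 18 of 29, estimated 0.021). Lipogenesis (-1.60, 16 of 23 lower, estimated 0.049), drug metabolism (-0.92, 20 of 32 lower, 21 alone, estimated 0.01) and retinoid metabolism (-0.92, 11 of 18 lower, estimated 0.049) fell. Fatty acid oxidation fell (median -0.74, adjusted p = 4.7e-06, 0.13 with an estimated correlation). The slide-block count was 4262, with 99.5% and 99.7% of genes the same way within slides 1 and 3 (matrix medians 2.66 and 2.01); median scaling moved the median of all genes from -0.037 to 0.174 and the share of higher calls from 51.4% to 70.5%.

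The comparison closest to the question of the series set VAD against VAS livers after ligation. It changed 2459 genes, 26.4% of those tested (1333 higher, 1126 lower, 798 at least 2-fold, 5 rats per group). A2m was 60.7-fold higher in VAD (5.92 (0.88), adjusted p = 2.9e-06, 98.4-fold without VAS BDL vehicle replicate 1), Mmp12 39.0-fold (5.28 (0.47), adjusted p = 2.5e-10), Lox 17.7-fold (4.15 (0.42), adjusted p = 2.3e-09) and Timp1 12.2-fold (3.61 (0.24), adjusted p = 1.6e-12). Col1a1 was 3.48-fold higher (1.80 (0.30), adjusted p = 2.2e-05), Ccl2 7.57-fold (2.92 (0.36), adjusted p = 1.5e-07, 2 of 5 VAS arrays detected it), and desmin Des, a stellate cell filament, rose by 2.84 (0.23, adjusted p = 2.9e-11). Trem2, a receptor of scar-associated macrophages, rose by 3.29 (0.35, adjusted p = 9.8e-09) and Krt19 by 1.41 (0.35, adjusted p = 0.002).

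Hepatocyte genes moved in both directions between the same groups. Cyp8b1 was 26.1-fold higher in VAD (4.71 (0.67), adjusted p = 1.4e-06). The protease inhibitor Serpina3c was 42.9-fold lower (-5.42 (0.39), adjusted p = 4.6e-12), Cyp2c11 35.3-fold (detected on 4 of 5 VAD arrays), the desaturase Scd 19.7-fold (-4.30 (0.57), adjusted p = 5.1e-07) and Cyp2c7, a retinoid-responsive P450, 13.8-fold (-3.78 (0.23), adjusted p = 1e-13). Nr0b2 was 4.75-fold lower (-2.25 (0.41), adjusted p = 6e-05) and Slc10a1 2.23-fold. Of retinoid genes, the retinol dehydrogenase Adh4 (-1.93 (0.34), adjusted p = 3.4e-05) and the retinal dehydrogenase Aldh1a1 (-1.73 (0.27), adjusted p = 5.9e-06) were lower. Lcn2 was higher by 2.17 (0.67, adjusted p = 0.014), but the adjusted p was 0.074 without VAS BDL vehicle replicate 3 (1.64) and 0.055 without replicate 5 (1.82). Cyp7a1 (-0.44, adjusted p = 0.59) and Alb (0.21, adjusted p = 0.25) did not pass, nor did Mki67, which 3 of 5 VAD and 0 of 5 VAS arrays detected (adjusted p = 0.19).

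Single immune genes differed in VAD against VAS BDL livers (5 rats per group), although the T and NK cell, antigen presentation and complement lists were not called (adjusted p = 0.21, 0.53 and 0.062). Cd8a, a coreceptor of cytotoxic T cells, was 3.97-fold higher (1.99 (0.32), adjusted p = 8.9e-06), while the cytotoxic granule genes Gzma (-1.45 (0.27), adjusted p = 7.9e-05) and Prf1 (-1.05 (0.23), adjusted p = 0.00071) and the chemokine Ccl5 (-1.13 (0.25), adjusted p = 0.00076) were lower. The class II genes RT1-Db1 (1.67 (0.26), adjusted p = 7.9e-06), Cd74 (1.30 (0.27), adjusted p = 0.00034) and RT1-Ba (1.18 (0.25), adjusted p = 0.00034) were higher, and the class I gene RT1-S3 was lower (-1.60 (0.17), adjusted p = 1e-08). The lectin pathway gene Mbl1 (-1.21 (0.19), adjusted p = 5.7e-06) and the terminal complement gene C8a (-1.06 (0.16), adjusted p = 3.7e-06) were lower. Gpx3, a secreted glutathione peroxidase, was 5.20-fold higher (2.38 (0.22), adjusted p = 6.8e-10), and the hepatokine Fgf21 3.72-fold higher (1.89 (0.43), adjusted p = 0.0011).

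8 lists differed between VAD and VAS BDL rats also with an estimated correlation. Matrix genes were higher (median 1.78, 33 of 38, 34 over the list alone, adjusted p = 2.7e-28, estimated 0.0019), as were macrophage (1.03, 14 of 18, 15 alone, adjusted p = 3.1e-10, estimated 0.033), neutrophil (1.10, 6 of 8, 7 alone, adjusted p = 0.00032, estimated 0.045), cytokine (0.75, 14 of 29, 15 alone, adjusted p = 0.0012, estimated 0.045), cholangiocyte (0.73, 12 of 16, 12 alone, adjusted p = 1.9e-06, estimated 0.015) and stellate cell genes (0.51, 6 of 12, 6 alone, adjusted p = 0.0054, estimated 0.033). Drug metabolism (-0.92, 19 of 32 lower, 19 alone, adjusted p = 5.7e-07, estimated 0.012) and hepatocyte genes (-0.40, 12 of 27 lower, 14 alone, adjusted p = 1.8e-06, estimated 0.045) were lower. Within slides 1 to 3 the matrix median was 2.37, 1.59 and 1.42, the macrophage median 1.35, 1.16 and 0.91, and the drug metabolism median -0.76, -0.81 and -0.96; with slide as a block they were 1.75, 1.06 and -0.88.

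8 further lists passed with the preset correlation only. Cell cycle (0.69, adjusted p = 6.4e-07, estimated 0.14), endoplasmic reticulum stress (0.29, adjusted p = 0.028, estimated 0.063) and acute-phase genes (0.20, adjusted p = 0.026, estimated 0.16) were higher. Lipogenesis (-0.98, adjusted p = 3.1e-05, estimated 0.059), retinoid metabolism (-0.44, adjusted p = 0.017, estimated 0.063), retinoid receptors and responsive genes (-0.48, -0.27 with bounds, adjusted p = 0.019, estimated 0.096), bile acid synthesis (-0.38, adjusted p = 0.022, estimated 0.25) and interferon-stimulated genes (-0.49, adjusted p = 0.026, estimated 0.27) were lower. Without VAD BDL vehicle replicate 4 the acute-phase and endoplasmic reticulum stress lists no longer passed (0.17 and 0.24, both adjusted p = 0.062), and the acute-phase median within slide 1 was -0.02. Without slide 3 the adjusted p of these lists was 0.18 and 0.082, and that of the interferon list 0.12. The retinoid receptor list had 0.063 in a fit to only the groups of the comparison. Not called were fatty acid oxidation (-0.05, adjusted p = 0.53), antigen presentation (-0.43, -0.25 with bounds, adjusted p = 0.53), bile transport (-0.31, -0.02 with bounds, adjusted p = 0.33), T and NK cells (-0.27, -0.17 with bounds, adjusted p = 0.21), complement (-0.16, adjusted p = 0.062), endothelium (0.44, 0.27 with bounds, adjusted p = 0.065), cholesterol synthesis (-0.15, adjusted p = 0.062), oxidative stress (-0.10, adjusted p = 0.28), erythroid (0.17, adjusted p = 0.61) and pancreas genes (0.63, 0.33 with bounds, adjusted p = 0.062). For no called list do median, mean and test differ in sign. The slide-block count was 2904, and 99.5%, 100% and 98.9% of genes moved the same way within slides.

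**Figure D2:**
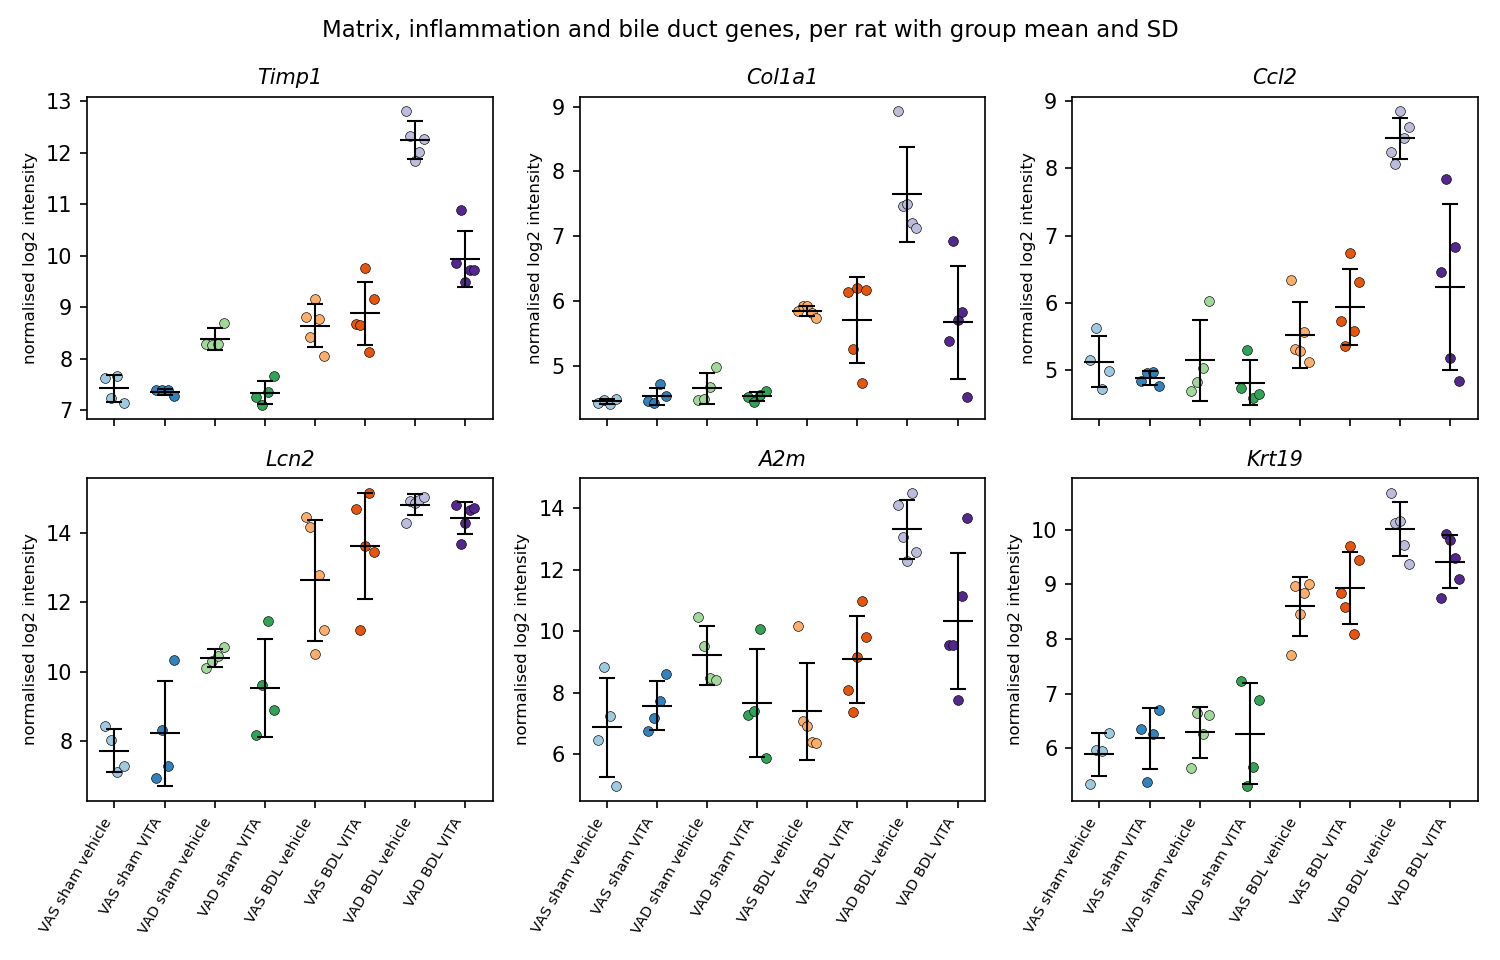
Normalised log2 intensity of fibrosis, bile duct and inflammation genes, 1 point per rat with group mean and SD, in 8 groups. Values are highest in VAD BDL vehicle rats for most genes.

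Whether ligation acted differently by diet was tested as an interaction, which 738 genes passed (396 higher, 342 lower in VAD). The ligation effect on Lox was larger in VAD rats by 4.93 (0.62, adjusted p = 3.5e-06, 4.26 without VAS sham vehicle replicate 3) and on Timp1 by 2.65 (0.36, adjusted p = 1.2e-05). For Cyp8b1 it was higher by 4.20 (1.00, adjusted p = 0.0061), because Cyp8b1 fell in VAS rats and did not pass in VAD rats. The ligation effect was lower in VAD rats for Serpina3c (-5.09 (0.58), adjusted p = 7.2e-07), Cyp2c11 (-4.60 (0.68), adjusted p = 2.9e-05), Nr0b2 (-3.32 (0.61), adjusted p = 0.00051) and Cyp2c7 (-2.92 (0.34), adjusted p = 7.6e-07). Krt19 (1.01, adjusted p = 0.27), A2m (3.58, adjusted p = 0.093) and Cyp7a1 (-2.14, adjusted p = 0.086) did not pass, so a diet difference in their ligation effect is not shown. A2m passed without VAS BDL vehicle replicate 1 (4.28, adjusted p = 0.03) or VAS sham vehicle replicate 4 (4.22, adjusted p = 0.049), and Cyp7a1 without VAD sham vehicle replicate 1 (-2.98, adjusted p = 0.0033). Matrix (median 1.59, 29 of 38 higher, 30 alone, adjusted p = 2.1e-30, estimated 0.0012), cholangiocyte (0.89, 6 of 16, 8 alone, estimated 0.024) and stellate cell genes (0.58, 5 of 12, 6 alone, estimated 0.046) held as higher. Drug metabolism (-0.71, 9 of 32 lower, 11 alone, estimated 0.013) and retinoid metabolism (-0.62, 3 of 18 lower, 6 alone, estimated 0.046) held as lower, while macrophage genes did not (0.48, adjusted p = 0.00011, estimated 0.22). With slide as a block 1086 genes passed, and median scaling moved the share of higher calls from 53.7% to 67.3%.

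Whether vitamin A injections move these differences was asked in VAD BDL rats. They changed 1582 genes (714 higher, 868 lower, 458 at least 2-fold, 5 rats per group). Mmp12 fell 14.4-fold (-3.85 (0.47), adjusted p = 3e-07), Postn, a matrix protein of activated fibroblasts, 9.93-fold (-3.31 (0.25), adjusted p = 3.3e-11, 1 of 5 treated arrays detected it), Lox 8.28-fold, Timp1 4.99-fold (-2.32 (0.24), adjusted p = 2.1e-08), Ccl2 4.63-fold and Col1a1 3.94-fold. Des fell by 2.11 on the log2 scale (0.23, adjusted p = 2.9e-08). Serpina3c rose 28.2-fold (4.82 (0.39), adjusted p = 1.2e-10), Cyp2c13 26.0-fold (4.70 (0.46), adjusted p = 6.6e-09), Cyp2c7 9.01-fold (3.17 (0.23), adjusted p = 1.7e-11), Cyp2c11 by 2.82 (0.45, adjusted p = 2.3e-05), Adh4 by 1.77 (0.34, adjusted p = 0.00022) and Gls2, a liver glutaminase, by 2.38 (0.26, adjusted p = 3.3e-08). Cyp8b1 fell 7.06-fold (-2.82 (0.67), adjusted p = 0.0024), 11.4-fold without VAD BDL VITA replicate 5 and 3.94-fold without replicate 1. Cyp26a1 rose at least 2.26-fold (3 of 5 treated arrays), but the adjusted p was 0.053 without VAD BDL VITA replicate 1 (1.26) and 0.078 in the authors' table (0.49). A2m fell 7.84-fold, but the adjusted p was 0.074 without VAD BDL VITA replicate 3 (-2.32), and the fall was 13.9-fold without replicate 5 (-3.80, adjusted p = 0.0015). Krt19 (-0.59, adjusted p = 0.27), Lcn2 (-0.38, adjusted p = 0.77) and Il1b (-0.62, adjusted p = 0.10) did not pass.

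7 lists held for the injections in VAD BDL rats. Matrix (median -1.26, 30 of 38 lower, 34 alone, adjusted p = 5.9e-27, estimated 0.0025), macrophage (-0.80, 13 of 18, 15 alone, adjusted p = 6.6e-09, estimated 0.039), cytokine (-0.62, 12 of 29, 14 alone, estimated 0.033) and stellate cell genes (-0.44, 5 of 12, 6 alone, estimated 0.039) fell. Drug metabolism (0.86, 15 of 32 higher, 19 alone, estimated 0.0095), retinoid metabolism (0.36, 7 of 18, estimated 0.039) and hepatocyte genes (0.32, 9 of 27, 11 alone, adjusted p = 1e-06, estimated 0.039) rose. Cholangiocyte genes (-0.52, adjusted p = 0.00076, estimated 0.052) and cell cycle genes (-0.50, adjusted p = 0.00011, estimated 0.25) lost their calls. With slide as a block 2043 genes passed, within slides 99.1%, 99.9% and 96% moved the same way, and the matrix median within slides was -1.65, -1.21 and -1.26. Slide 1 holds 1 vehicle array of this comparison. Slide 3 holds 1 treated array, VAD BDL VITA replicate 5, which lay apart from its group and is weighed below. In a fit to only the groups of the comparison 1014 passed. The share of higher calls was 45.1%, 35.4% under median scaling and 39.1% in the authors' table.

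**Figure D3:**
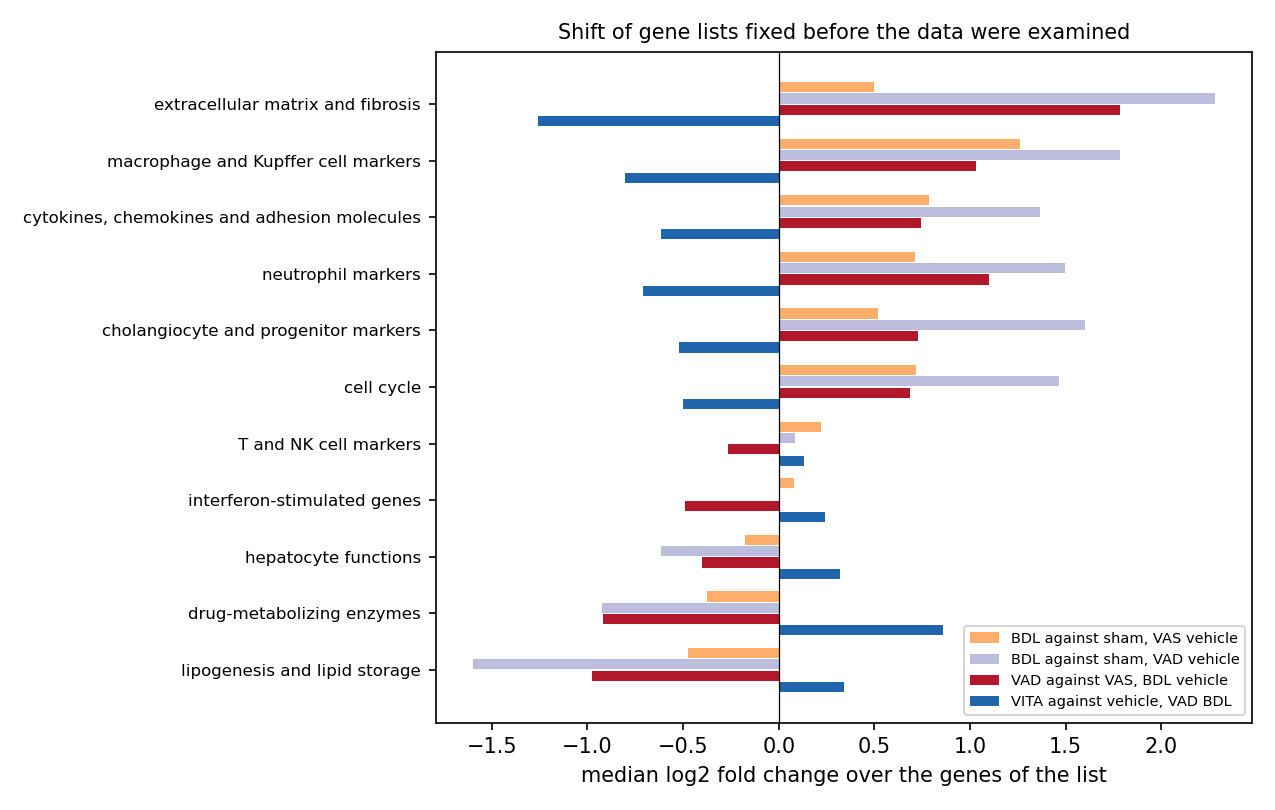
Median log2 change of selected gene lists in selected comparisons. These are ligation in VAS and in VAD vehicle rats, VAD against VAS after ligation, and the injections in VAD BDL rats. Other lists and comparisons are not drawn. Matrix, macrophage and cholangiocyte lists are highest after ligation in VAD rats, and matrix and macrophage lists fall with the injections in VAD BDL rats.

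This reversal shares the VAD BDL vehicle group with the diet comparison, so part of the inverse relation is built in. Across genes, which are not independent replicates, the diet effect after ligation and the injection effect in VAD BDL rats had r = -0.9 (covariance -0.2768). Simulated data without true effects gave -0.5 (-0.02557), and splitting the shared group gave -0.82 to -0.66 over 10 splits. 1362 genes were called in both, all in opposite directions, 754 and 608 by direction. Simulated data without effects that keep the shared arrays gave means of 372.6 and 287.4 for as many top genes, at most 400 and 323. With the shared arrays divided between the comparisons, 740 to 836 genes were called in both in opposite directions over 10 splits, where independent comparisons give 87.8 to 140.8. Timp1, Lox and Mmp12 are among the genes higher with deficiency and lower with the injections. The sham pair had r = -0.75 (covariance -0.09397, simulated -0.5 and -0.03201, split -0.42 to -0.25 over 6 splits), with 48 genes in both, all opposite, 20 and 28 by direction (simulated 7.7 and 6.5, at most 14 and 13). With the shared arrays divided it had 18 to 21 such genes, where independent comparisons give 0.1 to 0.4. Ligation in VAS and in VAD rats, which share no group, had r = 0.71 (simulated 0), with 1240 of 1253 genes in both the same way.

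In VAS BDL rats the question was whether injections act without deficiency. limma called 0 genes (473 at unadjusted p < 0.05, 5 rats per group). Cyp26a1, a direct retinoic acid target, was higher by 1.95 (0.48, unadjusted p = 3e-04, adjusted p = 0.71), and Timp1 by 0.24 (adjusted p = 0.91). A response of Cyp26a1 is therefore neither shown nor excluded. 11 lists passed camera with the preset correlation, led by macrophage (median 0.25, adjusted p = 0.00059, estimated 0.32), matrix (0.23, 0.15 with bounds, adjusted p = 0.00071, estimated 0.36) and cholangiocyte genes (0.25, adjusted p = 0.002, estimated 0.22), but 0 held with an estimated correlation and 0 passed fry. Without slide 3 these 3 lists had medians of 0.13, 0.03 and 0.16 and adjusted p of 0.16, 0.36 and 0.16. With slide as a block the count was 0; slide 1 holds no VAS BDL VITA array.

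The injection effect differed between diets in BDL rats for 1250 genes (535 higher, 715 lower in VAD). It was lower in VAD rats for Mmp12 (-5.07), Lox (-3.74 (0.59), adjusted p = 4.1e-05), Timp1 (-2.56) and Cd68, a macrophage gene (-1.56), and higher for Serpina3c (4.85), Cyp2c13 (4.36) and Cyp2c11 (4.25). 8 lists held with an estimated correlation: matrix (median -1.57, 29 of 38 lower, 30 alone, estimated 0.0057), drug metabolism (0.91, 11 of 32 higher, 15 alone, estimated 0.01), and, each with an estimated p of 0.038, macrophage (-1.04), cholangiocyte (-0.76), hepatocyte (0.44), cytokine (-0.44), stellate cell (-0.44) and endoplasmic reticulum stress genes (-0.41). With slide as a block 1475 genes passed and without slide 3 655, and median scaling moved the share of higher calls from 42.8% to 26% and the median of all genes from 0.005 to -0.132.

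The effect of the injections without ligation was asked in sham rats. In VAD sham rats they changed 121 genes (69 higher, 52 lower, 73 at least 2-fold, 4 rats per group). Cyp2c13 rose 46.7-fold (5.54 (0.51), adjusted p = 3.6e-09, 71.0-fold without VAD sham vehicle replicate 2), Cyp2c22 by 4.17 (0.34, adjusted p = 1.9e-10), Stac3, a muscle excitation-contraction gene, 13.2-fold (3.72 (0.46), adjusted p = 3.1e-06) and Obp3 10.8-fold (3.43 (0.48), adjusted p = 3e-05). Cyp2c12 fell 28.6-fold (-4.84 (0.36), adjusted p = 2.8e-11) and Ncald, a calcium sensor, 5.20-fold (-2.38 (0.38), adjusted p = 0.00019). Cyp26a1 rose at least 3.21-fold (4 of 4 treated and 0 of 4 vehicle arrays, adjusted p = 0.014), with adjusted p = 0.054 without VAD sham vehicle replicate 4 (2.33) and 0.19 in the authors' table (0.63). The retinoid receptor list passed (median 0.03, adjusted p = 0.014, estimated 0.26, 2 of 13 genes, 3 alone). All 121 genes moved the same way within slides 1 and 3, and 115 passed with slide as a block, 46 without slide 3 and 39 in a fit to only the groups of the comparison. The count was 74 without VAD sham VITA replicate 1, 70 without its replicate 2 and 67 without VAD sham vehicle replicate 4; median scaling moved the share of higher calls from 57% to 78.2%.

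In VAS sham rats limma called 2 genes for the injections, both lower (4 rats per group). They were Ncald (-1.99 (0.38), adjusted p = 0.036) and Hcfc2, a transcription cofactor, by at least 1.39-fold (adjusted p = 0.036). The count was 0 without VAS sham VITA replicate 1, 2 or 3 or VAS sham vehicle replicate 1, 2 or 3, was 1 without VAS sham vehicle replicate 4, and was 1 with slide as a block. Within slide 3 only 1 of these 2 genes moved the same way. With median scaling Ncald had adjusted p = 0.33 and Hcfc2 0.46. Of 8 lists called with the preset correlation, bile transport was lowest (median -0.26, adjusted p = 0.0012, estimated 0.11), and 0 held with an estimated correlation. The injection effect differed between diets in sham rats for 20 genes (13 higher, 7 lower), Cyp2c13 (5.52, 6.13 without VAD sham vehicle replicate 2), Cyp2c22 (4.02) and Cyp2c12 (-4.95) among them, and 23 passed with slide as a block and 8 without slide 3. That count ranged from 8 to 18 with 1 array left out; it was 8 without VAD sham vehicle replicate 3 or VAS sham VITA replicate 2, 9 without VAS sham VITA replicate 3 or VAS sham vehicle replicate 3, and 10 without VAD sham VITA replicate 3. It was 11 without VAD sham VITA replicate 1 or 2, VAD sham vehicle replicate 4 or VAS sham VITA replicate 4, 12 without VAD sham vehicle replicate 1 or 2 or VAS sham vehicle replicate 4, and 13 without VAS sham VITA replicate 1 or VAS sham vehicle replicate 2. Median scaling moved its share of higher calls from 65% to 87.5%. 6 lists passed with the preset correlation, led by cytokines (-0.38, adjusted p = 0.003, estimated 0.27) and macrophage genes (-0.39, adjusted p = 0.003, estimated 0.45), and 0 held. The macrophage call ended without VAD sham vehicle replicate 2 (-0.24, adjusted p = 0.059).

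**Figure D4:**
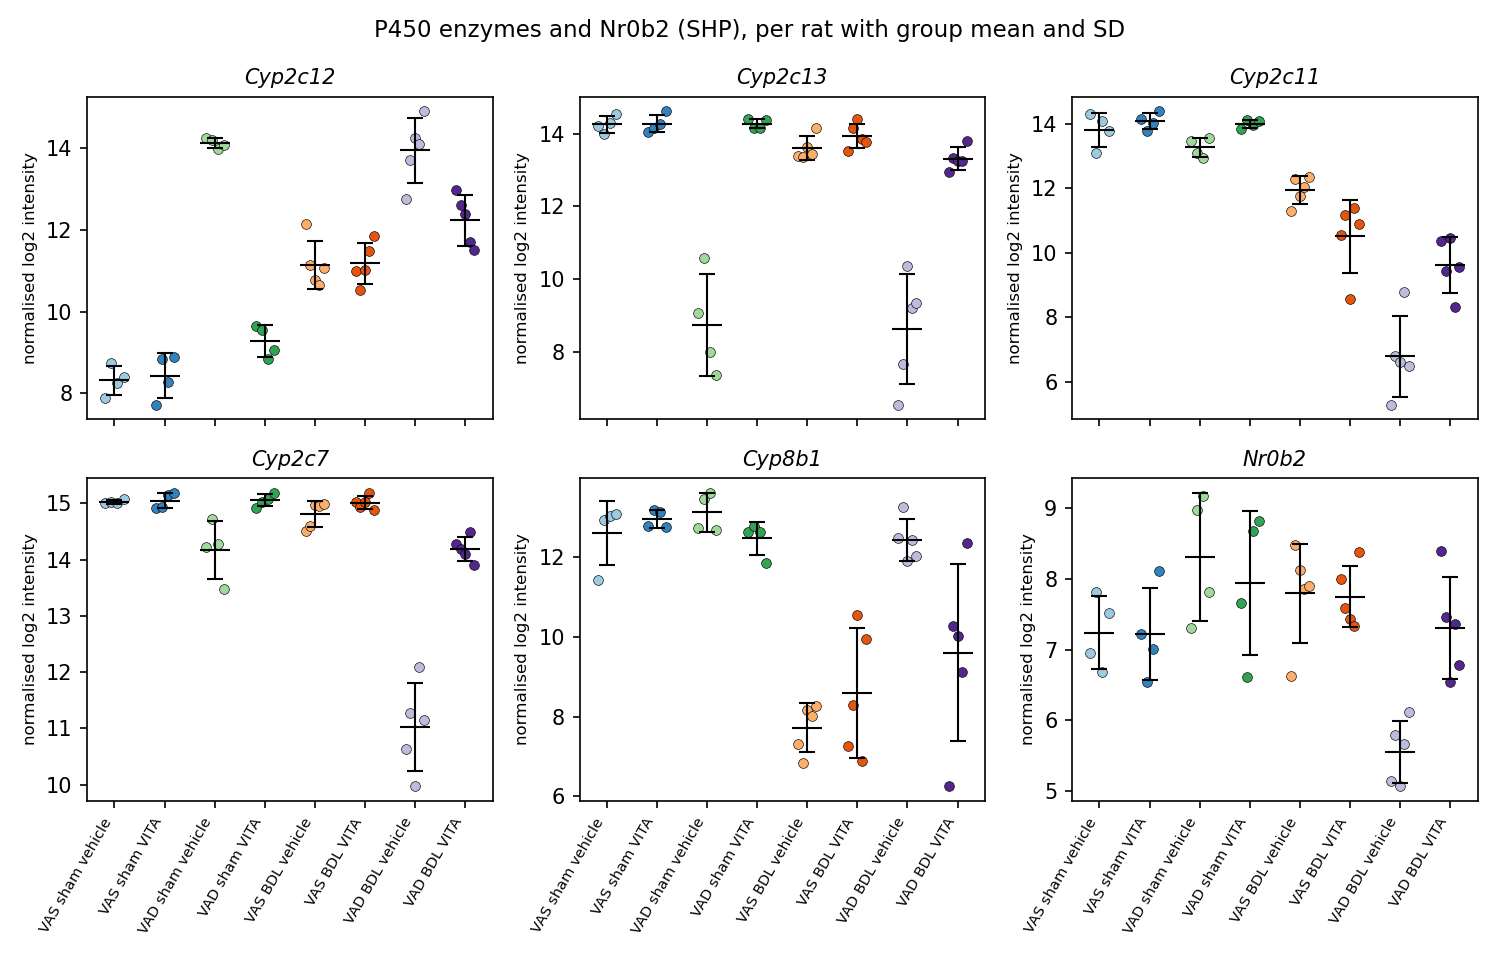
Normalised log2 intensity of P450 and bile acid genes, 1 point per rat with group mean and SD, in 8 groups. Cyp2c12 and Cyp2c13 change places in VAD sham vehicle rats and return with the injections. After ligation Cyp2c12 is also higher and Cyp2c13 lower in VAD than in VAS vehicle rats.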

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

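Of the tests weighed here, the loss of a male-type pattern, the lower share of hepatocytes and the array quality of VAD BDL VITA replicate 5 were written only after the result was seen; the others were written before.

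A sample far from the others of its group was looked for in 23 measures and 8 groups, 184 in all, and 16 were found; about 1 in 20 groups is expected by chance. In percent of probes detected, VAD BDL vehicle replicate 4 had 35.6 (others 37.5 to 38.1) and VAD sham vehicle replicate 4 had 29.2 (33 to 33.7). On principal component 4, VAD BDL VITA replicate 5 lay at 47.62 (-0.8815 to 6.604), and its Rarb was 9.28 (8.65 to 8.81). Cyp8b1 was 11.87 in VAD sham VITA replicate 4 (12.63 to 12.77) and 11.42 in VAS sham vehicle replicate 1 (12.92 to 13.09). Slc10a1 was 11.64 in VAD BDL VITA replicate 1 (12.17 to 12.27), and Krt7 was 5.93 in VAS BDL vehicle replicate 4 (5.02 to 5.23). In VAD BDL vehicle replicate 1 Col1a1 was 8.93 (7.13 to 7.5) and Lcn2 14.27 (14.85 to 15.03). Timp1 was 10.89 in VAD BDL VITA replicate 2 (9.49 to 9.86), 8.71 in VAD sham vehicle replicate 4 (8.26 to 8.29) and 7.28 in VAS sham VITA replicate 4 (7.39 to 7.4). Il1b was 6.4 in VAS BDL VITA replicate 3 (7.75 to 7.98) and 6.57 in VAS BDL vehicle replicate 5 (7.54 to 7.68). A2m was 10.17 in VAS BDL vehicle replicate 1 (6.37 to 7.08).

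Interactions are differences between groups in an effect. By diet the ligation effect differed for 738 genes. It was higher in VAD rats for Lox (4.93), Cyp8b1 (4.20), Rgs4 (4.15), Stac3 (3.64), Ccl2 (2.90), Timp1 (2.65), Col1a1 (1.60) and Krt7 (1.19). It was lower for Serpina3c (-5.09), Tsx (-4.86), Cyp2c11 (-4.60), Gsta2 (-3.41), Nr0b2 (-3.32) and Slc10a1 (-1.09). Ccl2, Rgs4, Col1a1 and Krt7 were below background on every array of both sham groups, Stac3 of both BDL groups and Tsx of VAS sham vehicle, so the sizes of these 6 are not known exactly. The value of Stac3 stems from its lower level in VAD than in VAS sham vehicle rats (-3.74), and shows no diet difference after ligation. Without VAS sham vehicle replicate 3 Lox was 4.26 and Stac3 3.02. The call of Col1a1 ends without VAD BDL vehicle replicate 1 (1.28, adjusted p = 0.058). The call of Krt7 ends without that array (1.14, adjusted p = 0.054) or VAS sham vehicle replicate 4 (1.04, adjusted p = 0.07), and that of Slc10a1 ends with median scaling (-1.18, adjusted p = 0.086).

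The injection effect differed by diet for 1250 genes in BDL rats: higher in VAD rats for Serpina3c (4.85), Cyp2c13 (4.36), Cyp2c11 (4.25), Gsta2 (3.95) and Nr0b2 (1.81), lower for Mmp12 (-5.07), A2m (-4.67), Rgs4 (-4.06), S100a4 (-3.77), Cyp8b1 (-3.69), Ccl2 (-2.63), Timp1 (-2.56), Col1a1 (-1.83), Cd68 (-1.56), Krt7 (-1.17) and Rarb (-0.68). Rarb had adjusted p = 0.41 without slide 3 (-0.28), and Nr0b2 had adjusted p = 0.2 in the authors' table (0.56). A2m was -5.50 without VAD BDL VITA replicate 5, -5.37 without VAS BDL vehicle replicate 1 and -4.02 without VAD BDL VITA replicate 3. Cyp8b1 was -4.38 without VAD BDL VITA replicate 5 and -2.85 without replicate 1. Without slide 3 A2m had adjusted p = 0.092, Ccl2 0.1 and Krt7 0.17. The injection effect differed by diet for 20 genes in sham rats: higher for Cyp2c13 (5.52), Cyp2c22 (4.02), Stac3 (2.95) and Rpp21 (1.73), lower for Cyp2c12 (-4.95), Cyp2c55 (-2.05), Pla1a (-1.91) and Ctse (-1.74). Cyp2c55, Pla1a and Ctse were below background on every array of 3 of the 4 sham groups, so their sizes are not known exactly. Without VAD sham vehicle replicate 2 Cyp2c13 was 6.13, and without VAS sham vehicle replicate 3 Stac3 was 2.33 (adjusted p = 0.11). In the authors' table Stac3 had adjusted p = 0.43, Pla1a 0.97 and Cyp2c55 0.91.

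Other splits of the same arrays into groups of the same sizes were counted, the real one included. As many genes changed in 1 of 35 splits for VAD against VAS sham vehicle (real 103, highest other 11) and VITA in VAD sham (121, 4). The same held in 1 of 100 for ligation in VAS (1617, 768), ligation in VAD (3769, 3006), VAD against VAS after ligation (2459, 886), VITA in VAD BDL (1582, 640) and the VITA by diet interaction in BDL rats (1250, 921). It held in 3 of 100 for the diet by surgery interaction (738, 1253) and the VITA by diet interaction in sham rats (20, 23), each below 0.05 although another split gave more. Chance is argued against at that level for those of these 9 that compare 2 groups, though splits that mix different groups also raise the error. For the interactions the splits exchanged diet within each operation, or injection within each diet. That removes the diet or injection effect itself, so they cannot decide whether an interaction is chance. Chance is not excluded for VITA in VAS sham (2 of 35 splits, real 2, highest other 2). For VITA in VAS BDL the real count was 0, so 100 of 100 splits had to reach it and the test could not decide (highest other 2).

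The first pattern weighed is the exchange of Cyp2c12 and Cyp2c13 in VAD sham vehicle livers. It was not confined to sham rats. After ligation VAD vehicle rats also had higher Cyp2c12 (2.78, limma adjusted p = 3.8e-08) and lower Cyp2c13 (-4.98, adjusted p = 4.9e-10) than VAS vehicle rats. Within slides 1 and 3, 100% of the genes changed in sham rats kept their direction, but they were chosen from the same arrays, which favours that result. It argues only weakly against a slide difference. In sham rats 132 genes passed with slide as a block and 37 without slide 3. Female animals are argued against by Cyp2c11 above background on 4 of 4 arrays. A loss of the male-type pattern beyond the genes already seen was not found in sham rats. Without those genes, 8 male- less 7 female-predominant genes averaged 4.72 in VAD and 4.63 in VAS rats, a difference of 0.09 (exact permutation p = 0.8, two-sided, 70 splits). Cyp2c12, Cyp2c13 and Obp3, left out here, all moved towards a loss, and the female-predominant Cyp2c7 (-0.86), kept in, works against finding it. A partial loss in sham rats therefore stays open. After ligation the same mean was 3.35 in VAD (2.83 to 3.77) and 4.39 in VAS vehicle rats (4.25 to 4.57). With the injections it was 3.47 and 3.95. It still holds the male-predominant Cyp2c11 (-5.14) and the female-predominant Cyp2c7 (-3.78), already seen to fall there, whose falls move it in opposite directions. Other male-predominant genes in it were also lower: Mup4 (-2.60), Cyp3a2 (-2.56), Mup5 (-1.96) and Cyp3a18 (-1.02, limma adjusted p = 0.008 or less for each). Cyp2a2, Sult1e1 and Hsd11b1 did not pass, and no female-predominant gene in it was called higher. The prediction was written for sham rats, so this mean is no planned test and a wider loss after ligation stays open. In VAD rats the injections moved both P450 genes back: Cyp2c12 by -4.84 in sham and -1.70 in BDL rats, Cyp2c13 by 5.54 and 4.70. A direct retinoid action on Cyp2c12 and Cyp2c13 was not tested and is only a hypothesis.

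The second pattern is the higher matrix list in VAD BDL vehicle livers. A slide difference is argued against by a median of 1.42 in the lowest of the 3 slides. Matrix genes rose more than T and NK cell genes by 1.97 (SE 0.17, exact permutation p = 0.0079, two-sided, 252 splits, 5 rats per group). That cannot decide on a lower share of hepatocytes, because the 2 lists were set against each other after their shifts were seen. It also assumes that T and NK cells did not themselves change, while single genes of that list moved in both directions, Cd8a higher and Gzma lower. Hepatocyte genes were lower (median -0.40), and macrophage (1.03), cholangiocyte (0.73) and stellate cell genes (0.51) were higher. Endothelial genes (0.44, 0.27 with bounds) and T and NK cell genes (-0.27) were not called. A lower share of hepatocytes, more matrix-producing cells and more transcript per cell all stay open, and arrays of whole liver could not separate them.

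The third pattern is VAD BDL VITA replicate 5, apart from its group on principal component 4. Its A2m was 13.67 (others 9.51 ± 1.39 SD), Cyp8b1 12.36 (8.92 ± 1.85) and Cdk1 5.71 (8.38 ± 0.09). Poor array quality is argued against by 33.6% of probes detected, within the range of the other arrays. The test of a wrong label, written beforehand, was closeness to another group, and it was met: centred values correlated 0.16 with VAD BDL vehicle and 0.05 with its own group. A demand that it reach the level of that group's own arrays (lowest 0.76) was added after the result and was not met. The test made no allowance for slide. Replicate 5 is the only array of its group on slide 3, while VAD BDL vehicle has 2 there. Deviations of arrays of these groups correlated 0.14 on average within a slide and -0.06 between slides. The test therefore cannot separate a wrong label from a shared slide. A wrong label, an outside sample and an animal that responded differently all stay possible.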

How the results depend on the processing

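Of 749 gene values 461 passed, and 380 of these kept direction and side of the threshold under every alternative but the added one. Of 117 list shifts that passed, 77 kept their call, not counting the estimated correlation, under which 77 lost it. 1 value reversed. Gene values that passed neither in the main fit nor under a setting changed sign 146 times, counted for each value and setting, the added one included. Replicate numbers do not pair, so that block is a check only. Only the groups of the comparison (fewer arrays set the error): VAD against VAS sham 41, VITA in VAD BDL 1014, VITA in VAD sham 39, VITA in VAS sham 0, VITA by diet in sham 10. Without slide 3 (fewer arrays, chosen after seeing the data): VAD against VAS sham 37, VITA in VAD sham 46, VITA in VAS sham 8, VITA by diet in BDL 655 and in sham 8; the neutrophil list with VITA in VAS BDL was 0.07 (adjusted p = 0.93), its test opposite in sign. For VITA in VAS sham the count was 0 with normexp, median scaling, the authors' table or no filter and 1 with slide or replicate as a block. For VITA by diet in sham it was 13 with normexp, 8 with median scaling, 8 in the authors' table and 10 with no filter; the cause was not tested. With 1 array left out counts ranged from 49 to 109 (VAD against VAS sham), 1262 to 1520 and 3365 to 3692 (ligation in VAS and VAD), 2110 to 2369 (VAD against VAS BDL), 546 to 757 (diet by surgery), 1269 to 1573, 0 to 0, 67 to 120 and 0 to 2 (VITA in VAD BDL, VAS BDL, VAD sham, VAS sham), 962 to 1415 and 8 to 18 (VITA by diet in BDL, sham). Signal over background limits genes near the background: Col1a1 after ligation in VAS passed by at least 1.05-fold and had adjusted p = 0.11 in the authors' table; the cause was not tested.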

Other observations

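The comparisons in this part were chosen only after the result was seen. They set the injected VAD rats against VAS rats. VAD BDL VITA against VAS BDL vehicle changed 31 genes (17 higher, 14 lower, 1091 at unadjusted p < 0.05, 5 rats per group), and 75 with slide as a block. Of the 2459 genes that differ by diet after ligation with vehicle, 27 changed here in the same direction, and the median change in that direction was 0.24, against 0.77 in the vehicle comparison. The sham counterpart had a median of 0.31, against 1.14. Both reuse the VAS vehicle arrays of the vehicle comparison, so part of these values is built in. The vehicle medians are raised by the choice of genes that passed. VAD against VAS with VITA after ligation changed 3 genes (0 higher, 3 lower, 1157 unadjusted), and 6 with slide as a block. The second comparison shares no array with the vehicle comparison. Over the 2459 genes its median change in the direction of the vehicle comparison was 0.08, also with slide as a block. In sham rats limma called 0 genes for VAD VITA against VAS vehicle (449 unadjusted, 2 with slide as a block). It called 0 for VAD against VAS with VITA (342 unadjusted, 0 with slide as a block), with a median over the 103 genes of the vehicle comparison of 0.13, and 0.17 with slide as a block.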
